A study of Homo sapiens with 6 samples.

How the data were processed

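The series holds 6 RNA-seq libraries of the human gastric cancer line HGC-27, 3 from cells with a control shRNA and 3 from cells with an shRNA against GXYLT2, and the sample titles gave each library its group and replicate number. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were prepared with an Illumina stranded kit for messenger RNA by ligation. Per the submitters' processing notes, fastp, HISAT2 and StringTie were used with the GRCh38.p13 build; their versions, their roles, the counting step and the annotation release are not given in the sources used here. The authors deposited 1 table of estimated counts per gene, not normalized, of which 12.3% of the values were not whole numbers. Gene length, which the authors deposited as another column of the table, has no definition in the sources used here and was used only in the GC content and length offsets. Whether the counting used strand is not given, so reads of overlapping and antisense genes could not be told apart. The shRNA sequence is also not given in the sources used here.

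The table listed 62703 genes by Ensembl identifier, of which 41737 had a symbol and 31712 had 0 counts in all 6 libraries. Gene types, positions, GC content and 3' UTR sequences came from GENCODE release 29 on GRCh38, to which 58279 genes (92.9%) matched by identifier. Estimated counts were rounded to whole numbers. Library totals were 17291138 to 24898425, and the tested genes held 99.9% of the counts. At this depth a gene at 5.63 CPM, the GXYLT2 level after knockdown, rested on 119 to 154 counts per library. Pairs of libraries were compared by a chi-square statistic of their counts per degree of freedom, which was 1.98 to 4.02 between shControl libraries, 5.84 to 10.9 between shGXYLT2 libraries and 8.65 to 18.7 between groups, so no library was taken as a copy of another.

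Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr by group at its default settings, scaled by TMM factors and fitted with the robust quasi-likelihood model, with group as the only term and all 6 libraries in the fit. P-values were two-sided and adjusted by the Benjamini-Hochberg method over 15693 genes, with a threshold of 0.05. CPM values are scaled by TMM, except the levels of leukocyte markers and the summed CPM of lists, which are scaled to library totals alone. Means are given with the SD over 3 libraries. The GXYLT2 level was also compared by an exact permutation test. Gene lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01, for lists with at least 5 tested members and with Benjamini-Hochberg adjustment over 29 lists, and again with an estimated correlation and with fry.

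The design, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined. The 31 lists covered glycosylation of EGF repeats, Notch components and Notch targets, S-phase, G2/M, CDK inhibitors and p53 targets, apoptosis, epithelial junctions, mesenchymal markers, matrix proteases and invasion, integrins, stemness, Wnt, YAP and TAZ, TGF-beta, interferon, NF-kB, immediate early genes, hypoxia, the unfolded protein response, cholesterol synthesis, oxidative phosphorylation, ribosomal proteins, mitochondrially encoded genes, histones, nuclear RNAs as a sign of RNA quality, gastric lineage, leukocytes, endothelium, fibroblasts and other glycosyltransferases. Named genes are GXYLT2, the 10 largest rises and 10 largest falls among protein-coding genes past the threshold with a mean log2 CPM of at least 3 and groups that did not overlap, up to 3 risen and 3 fallen members of each list by adjusted p, or the 2 most abundant members of a list with none, and any member of the lists on EGF repeat glycosylation, Notch targets and stemness. CKMT1A, MKI67, PTPRC, CD74 and the low-level genes named in the closing observations, were chosen outside this rule. The values of 1 gene that the rule names are not reported here.

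Words in 3' UTRs were searched after the fold changes were known. The presence of each of 16384 possible 7-base words in the longest annotated 3' UTR (at least 100 bases) of 12372 genes was related to the log2 fold change by regression, the strongest word was chosen in a random part of the genes, and its t was then read in the other, equal part. Words among the 5 lowest t that share 6 bases in a row with it were counted beside it. Words were tested on shuffled fold changes too, where 10 of 10 planted words were found. The planted log2 shift of 0.12 was close in size to that of the strongest word (-0.123), so weaker words were not tried. Without a planted word the lowest t was -5.40, and the best rank of a chosen word in the other part was 1702. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

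The model was tested on counts simulated for the comparison of shGXYLT2 with shControl, with 15354 genes tested. In these counts 200 drawn genes were changed, and the members of the stemness list were shifted 1.5-fold as well. The model found 77.6% of drawn genes changed 1.5-fold, 89.6% of those changed 2-fold and 100% of those changed 4-fold. All drawn genes had a shControl mean of at least 1 CPM, so weaker genes were not tried. Of 209 calls, 4.3% were of genes that had not been changed. With nothing changed, 2 genes and 0 lists passed. In the counts with the shifted stemness list, 2 other lists passed camera as well. Lists such as those of Wnt targets and integrins share members with it, so these 2 calls need not be false. Genes were simulated independently of each other, while the estimated correlation within a list reached 0.646 in the data. The simulation therefore could not show false list calls that arise from correlated genes.

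The alternatives were DESeq2 1.42.0 size factors, library totals alone, upper-quartile factors, the DESeq2 test, limma-voom, no filter, a filter at 1 CPM in at least 3 libraries, no robust estimation, a block by replicate number, protein-coding genes only, GC content and length offsets per library (loess, span 0.3; 96.3% of tested genes had a GC value) without and with the block, each library left out in turn, a test against a 1.2-fold change, camera with an estimated correlation, fry, and lists without GXYLT2. The fit to genes without the 3' UTR word kept GXYLT2 and the searched genes that lacked the word. Genes without a searched 3' UTR were left out of it too. This fit, and counting lists at an unadjusted p with an estimated correlation, were chosen after seeing the data.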

Results

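Messenger RNA was sequenced from HGC-27, an established human gastric cancer cell line, grown in medium with 10% fetal bovine serum. Lines stably expressing an shRNA against GXYLT2 (shGXYLT2) were compared with lines expressing a control shRNA (shControl), with 3 libraries in each group. The comparison asks how a lower GXYLT2 level alters genes linked to proliferation, invasion and stemness. Estimated counts totalled 17512826, 17291138 and 22540099 in shControl replicates 1 to 3, and 24898425, 24674750 and 22188073 in shGXYLT2 replicates 1 to 3. The 10 most abundant genes took 7.0% to 7.40% of the counts of a library, and mitochondrial genes took 5.79% to 5.81% in shControl and 5.85% to 6.45% in shGXYLT2. The labels do not say whether the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The common biological coefficient of variation was 6.50%, and the first principal component, which held 37.9% of the variance, separated the groups.

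GXYLT2 encodes glucoside xylosyltransferase 2, an enzyme that adds xylose to O-linked glucose on the EGF repeats of Notch receptors. The gene (ENSG00000172986) lies on the plus strand of chromosome 3, from base 72888073 to 72998138 (GRCh38). Its estimated counts were 360, 390 and 460 in the shControl libraries and 132, 154 and 119 in the shGXYLT2 libraries, which gave 20.7, 22.8 and 20.2 CPM, counts scaled to library size, against 5.27, 6.27 and 5.34 CPM. The mean fell from 21.3 ± 1.40 to 5.63 ± 0.556 CPM (SD, n = 3 each), 73.5% lower, in all 3 shGXYLT2 libraries, with an exact two-sided permutation p = 0.1, the smallest that 3 against 3 libraries can give. In the model across all genes the log2 fold change was -1.91 (SE 0.109, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 6.3e-10). GXYLT1, the paralog with the same enzymatic activity, lies on the minus strand of chromosome 12, from base 42081845 to 42144879. Its level fell 2.07-fold, from 73.3 ± 3.35 to 35.4 ± 4.39 CPM (SD, n = 3 each), with an edgeR adjusted p of 3.7e-08.

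**Figure D1:**
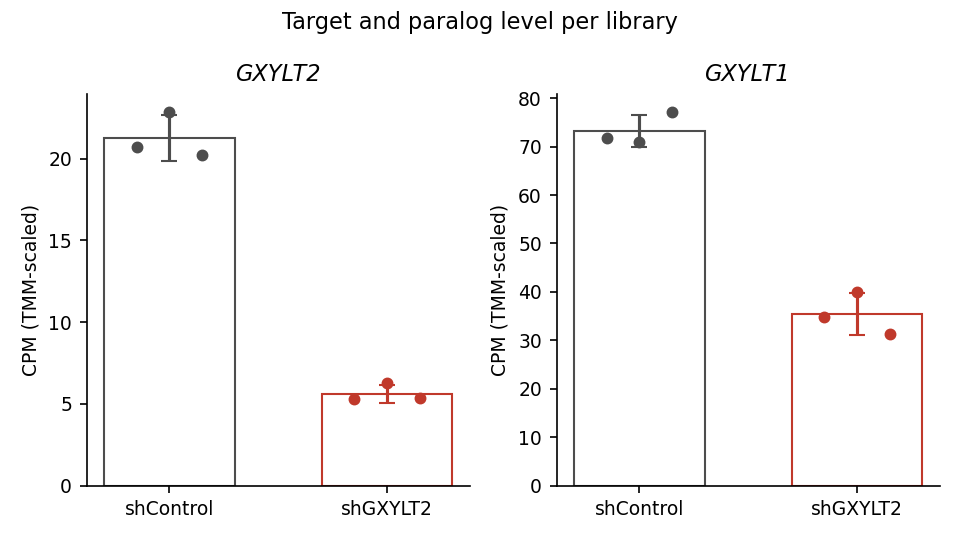
Level of GXYLT2 and of its paralog GXYLT1 in CPM, with 1 point per library, bars for the group means and error bars for the SD over 3 libraries. All 3 shGXYLT2 libraries lie below all 3 shControl libraries for both genes, and the GXYLT1 mean fell from 73.3 to 35.4 CPM.

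The shGXYLT2 libraries differed from the controls in 1907 of 15693 tested genes (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05), of which 833 rose and 1074 fell. The balance depended on the scaling and the filter, since upper-quartile factors gave 1024 rises and 963 falls and testing without a filter gave 1038 and 1057. Most changes were small, with a median absolute log2 fold change of 0.39, and 195 genes changed at least 2-fold, 97 upward and 98 downward. Among genes with a mean log2 CPM of at least 3 and groups that did not overlap, the largest rise was that of LRP2, the endocytic receptor megalin, from 2.72 ± 0.0906 to 21.1 ± 0.780 CPM (SD, n = 3 each; 7.75-fold, edgeR adjusted p = 7.1e-12). The secreted glycoprotein STC1 rose 4.67-fold and CHODL, a membrane protein with a lectin domain, rose 4.02-fold, to 54.1 CPM. FN1, which encodes the matrix protein fibronectin, rose 2.04-fold from 38.7 to 78.7 CPM, and the neural adhesion molecule CNTN1 rose 2.16-fold to 219 CPM. GNG4 (3.40-fold), CKMT1B (3.0-fold), RAB3B (2.47-fold), PPM1E (2.03-fold) and EPHA7 (2.01-fold) made up the rest of the 10 largest rises. CKMT1B is uncertain, since CKMT1A is a near-identical copy that the counting could have split; CKMT1A rose 3.18-fold.

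Above the same floor of 3 in mean log2 CPM, the largest fall after GXYLT2 was that of CIAO2A, a factor of cytosolic iron-sulfur protein assembly, from 67.0 ± 4.03 to 22 ± 3.14 CPM (SD, n = 3 each; 3.05-fold lower, edgeR adjusted p = 6.3e-10). DCK, the kinase that phosphorylates deoxycytidine, fell from 70.2 to 27.0 CPM (2.60-fold lower), and the autophagy receptor SQSTM1 fell from 127 to 54.5 CPM (2.33-fold lower). MAT2B, a subunit of methionine adenosyltransferase, fell to a level 2.34-fold lower, and DKK1, a secreted Wnt antagonist, fell from 34.4 to 14.7 CPM (2.33-fold lower). The remaining falls among the 10 largest were NEK7 (2.48-fold lower), LRATD2 (2.48-fold lower), COPS8 (2.27-fold lower), EMP1 (2.26-fold lower) and STK17B (2.25-fold lower). The 3 shGXYLT2 libraries lay apart from all 3 shControl libraries in 1876 of the 1907 changed genes and in 30.4% of all tested genes, where chance gives 10%. The count of changed genes was 990, 1152 and 960 without shControl replicates 1, 2 and 3 in turn, 3017 with GC content and length offsets, and 403 when tested against a 1.2-fold change.

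**Figure D2:**
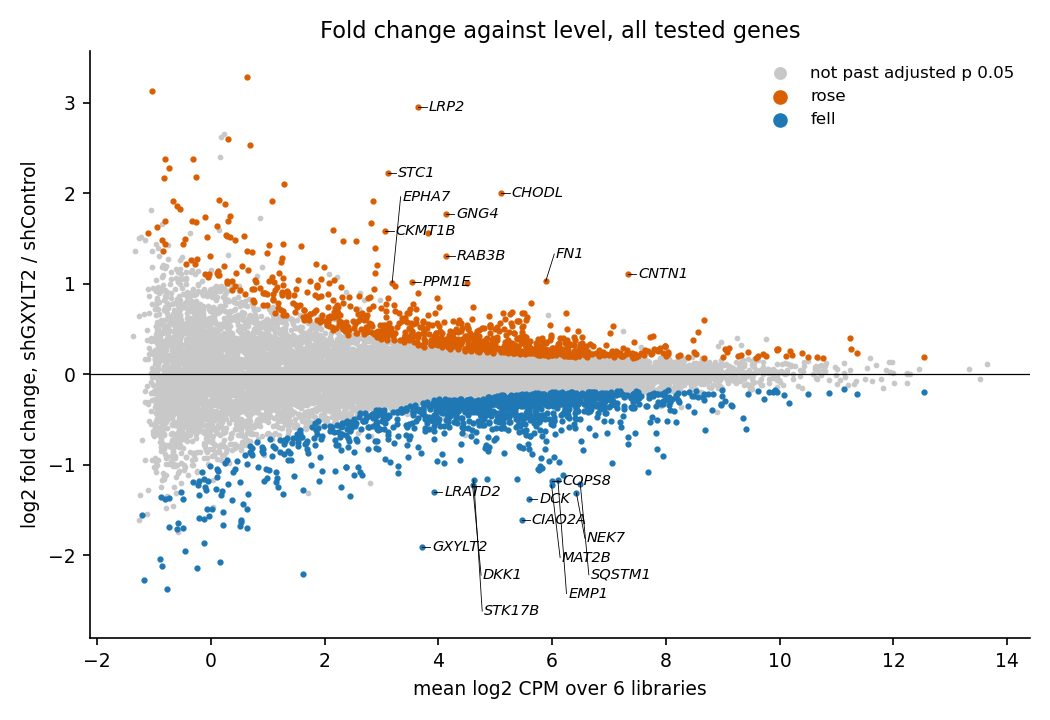
Log2 fold change, shGXYLT2 over shControl, against mean log2 CPM over 6 libraries, with 1 point per tested gene (15693 genes), rises in orange and falls in blue. The labelled genes are GXYLT2 and the 10 largest rises and falls among well expressed genes, with LRP2 highest at 7.75-fold.

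Many of the genes that fell shared the 7-base word GACTCAT in the 3' UTR of their transcripts. A search of all 7-base words for an association with the fold change was added after the fold changes had been computed. Among 12372 genes with a searched 3' UTR, 1033 (8.35%) held this word, and it was held by 246 of the 969 that fell (25.4%) and by 39 of the 758 that rose (5.1%). Of genes with the word 23.8% fell, against 6.4% of genes without it, and the word was held by 24 of 73 genes that fell at least 2-fold. These counts include the genes on which the word was chosen. The remaining 723 fallen genes lacked it. DCK, NEK7, LRATD2, SQSTM1, COPS8 and STK17B carried it, as did GNG4 and RAB3B among the largest rises. GXYLT1 held 2 copies in its 3' UTR of 5941 bases. Of 3 GXYLT2 transcripts 2 held the word, at base 645 of the longest (3260 bases) and outside its 3' UTR.

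**Figure D3:**
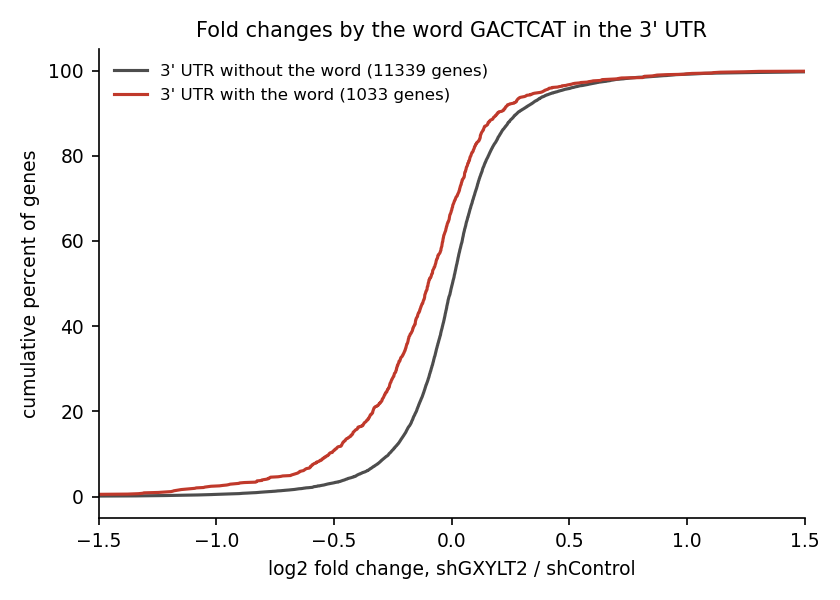
Cumulative percent of genes by log2 fold change, shGXYLT2 over shControl, for the 1033 genes whose 3' UTR holds the word GACTCAT (red) and for searched genes without it (grey). The curve of genes with the word lies to the left, with a median log2 fold change of -0.10 against 0.003.

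Among genes that glycosylate EGF repeats, those that fell were the target and its paralog. Of 12 tested members of this list 2 fell, GXYLT2 and GXYLT1, and 10 did not pass, also when adjusted over the list alone (limma camera adjusted p = 5.9e-04 and adjusted p = 0.155 with an estimated correlation; 3.6e-06 to 0.156 over the alternatives). Without GXYLT2 in the list the camera adjusted p was 0.156, and with limma-voom it was 0.10. Among genes without the word it was 0.0631, in a fit that kept GXYLT2 but left out GXYLT1, which carried the word. XXYLT1, which adds the next xylose, averaged 56.4 CPM in shControl and 50.2 CPM in shGXYLT2 (edgeR adjusted p = 0.13). POGLUT1, which adds the O-linked glucose, averaged 21.8 and 23.5 CPM (adjusted p = 0.42).

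Of 26 tested Notch receptors, ligands and processing factors 5 rose and 1 fell, the same numbers as adjusted over the list alone (camera adjusted p = 0.357). The receptor NOTCH2 rose from 199 ± 2.09 to 242 ± 4.41 CPM (SD, n = 3 each; log2 fold change 0.28, edgeR adjusted p = 0.0017). MIB1, the ubiquitin ligase that drives ligand endocytosis, fell from 155 to 108 CPM (log2 fold change -0.52) and carried the word. The rises numbered 1, 3, 1 and 3 without shControl replicates 1, 2 and 3 and shGXYLT2 replicate 1. Among 16 tested Notch targets 1 rose and 2 fell, or 3 and 3 adjusted over the list alone, and 2 and 2 with upper-quartile factors. The median (0.030) and the camera direction were positive and the mean (-0.040) negative, at a camera adjusted p of 0.882. With 1 library left out the median ran from -0.027 to 0.138, and the direction was down without shControl replicate 3 or shGXYLT2 replicate 3. MYC, a growth-promoting transcription factor, fell from 268 to 212 CPM (adjusted p = 0.0023, 5.9e-06 to 0.0968 over the alternatives). BMP2 rose, a call kept only without shGXYLT2 replicate 2, and HES6 fell, a call kept only without shControl replicate 3 or shGXYLT2 replicate 3, among the 6 fits that left out a library (adjusted p of 0.0077 to 0.119 and 0.010 to 0.208 over the alternatives). The list held 0 risen members without shControl replicates 1, 2 or 3 or shGXYLT2 replicate 1, 3 without shGXYLT2 replicate 2, and 1 fallen member without shControl replicates 1 or 2 or shGXYLT2 replicates 1 or 2. HES1, a direct Notch target, averaged 4.62 and 4.70 CPM (adjusted p = 0.93), and NOTCH1 averaged 41.4 and 42.0 CPM (adjusted p = 0.91).

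In the list of S-phase and DNA replication 1 of 39 tested members rose and 6 fell, or 2 and 6 adjusted over the list alone. This balance depended on the scaling, since upper-quartile factors gave 4 rises and 6 falls. The camera direction was up while the median (-0.017) and mean (-0.009) were negative (adjusted p = 0.882); with 1 library left out the median ran from -0.045 to 0.041, and without shControl replicate 3 the direction was down. CCNE2, a cyclin of S-phase entry, fell from 33.8 to 25.7 CPM (log2 fold change -0.40, edgeR adjusted p = 0.0037). Without shControl replicates 1, 2 and 3 the falls numbered 1, 2 and 3, and without shGXYLT2 replicates 2 and 3 the rises numbered 2 and 5. Of 39 tested genes of G2/M and mitosis 1 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.597). BUB1B, a kinase of the spindle checkpoint that carried the word, fell from 215 ± 3.68 to 138 ± 9.66 CPM (SD, n = 3 each; edgeR adjusted p = 6.1e-07), and HMMR rose from 70.4 to 88.4 CPM (adjusted p of 3.7e-06 to 0.0566 over the alternatives). Leaving out shGXYLT2 replicate 1 or 3 gave 2 or 5 rises in this list, and leaving out shControl replicate 2 or shGXYLT2 replicates 1 or 3 gave 2 falls. MKI67, the proliferation marker Ki-67, averaged 422 ± 19.9 and 391 ± 32.5 CPM (SD, n = 3 each; edgeR adjusted p = 0.29).

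Mesenchymal genes moved in both directions, more of them downward. Of 27 tested members 3 rose and 11 fell, or 5 and 12 adjusted over the list alone, with a median log2 fold change of -0.12 (camera adjusted p = 0.0324 and adjusted p = 0.55 with an estimated correlation; 0.0055 to 0.549 over the alternatives). COL1A1, the alpha 1 chain of type I collagen, fell from 824 ± 20.4 to 542 ± 48.2 CPM (SD, n = 3 each; edgeR adjusted p = 2.0e-06), and COL1A2, its alpha 2 chain, rose from 51.9 to 66.3 CPM (adjusted p = 0.0028), beside the rise of FN1. LOXL2, a collagen-crosslinking oxidase, and the surface glycoprotein THY1 fell by 0.49 and by 0.47 on the log2 scale, and these were the 2 fallen members with the word. The camera adjusted p was 0.0503 without shControl replicate 2 and 0.103 without shGXYLT2 replicate 2, and the falls numbered 7 without shControl replicate 1 and 7 without shControl replicate 2. The median was -0.20 without shGXYLT2 replicate 1. The list's camera adjusted p was also 0.0712 with a filter at 1 CPM and 0.107 among genes without the word, and its fry adjusted p was 0.0559.

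Of 29 tested genes of matrix proteolysis and invasion 2 rose and 5 fell, or 3 and 6 adjusted over the list alone (camera adjusted p = 0.153, range over the alternatives 0.0279 to 0.664). EZR, which links the actin cortex to the membrane, fell from 140 to 104 CPM (log2 fold change -0.43, edgeR adjusted p = 2.4e-04). The protease inhibitor TIMP3 fell from 134 to 105 CPM, and ROCK1, a kinase of actomyosin contraction that carried the word, fell from 195 to 150.5 CPM. Without shControl replicate 3 the list passed camera (adjusted p = 0.0279) with 1 rise, and without shControl replicates 1 and 2 it held 0 rises and 1 rise. Of 34 tested genes of integrins and focal adhesion 2 rose and 4 fell, or 3 and 5 adjusted over the list alone (camera adjusted p = 0.847). The laminin chain LAMB1 rose from 281 to 326 CPM; its edgeR adjusted p was 0.079, 0.081, 0.060 and 0.074 without shControl replicates 1, 2 and 3 and shGXYLT2 replicate 1 (5.5e-04 to 0.178 over the alternatives). The actin crosslinker ACTN1 fell from 230 to 196 CPM; its adjusted p was 0.088, 0.090 and 0.055 without shControl replicates 1 and 2 and shGXYLT2 replicate 2 (3.5e-04 to 0.319 over the alternatives). The falls numbered 0, 0 and 1 without shControl replicates 1 and 2 and shGXYLT2 replicate 2; the rises numbered 1, 0, 0, 0 and 5 without shControl replicates 1, 2 and 3 and shGXYLT2 replicates 1 and 3. Of 12 tested epithelial junction genes 0 passed the edgeR test, also adjusted over the list alone, with 2 at an unadjusted p below 0.05 (camera adjusted p = 0.776).

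Stemness markers also moved in both directions. Of 31 tested members 4 rose and 5 fell, or 5 and 8 adjusted over the list alone (camera adjusted p = 0.225; fry adjusted p = 0.0415; range over the alternatives 0.0415 to 0.549). ALDH3A1, an aldehyde dehydrogenase, rose from 24.4 to 35.4 CPM (log2 fold change 0.54, edgeR adjusted p = 1.4e-04), and the kinase DCLK1 rose from 0.616 to 1.75 CPM. BMP4, a secreted ligand of the BMP pathway, fell from 36.0 ± 0.355 to 20.5 ± 1.87 CPM (SD, n = 3 each; edgeR adjusted p = 1.6e-06), and the intermediate filament gene NES fell from 76.5 to 58.9 CPM. CD44, a hyaluronan receptor, averaged 77.7 and 68.3 CPM (adjusted p = 0.064). Without shControl replicate 3 the rises numbered 2.

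Among signalling lists, targets of YAP and TAZ gave the lowest camera p. Of 23 tested members 0 rose and 12 fell, or 0 and 15 adjusted over the list alone, with a median log2 fold change of -0.27 (camera adjusted p = 4.0e-08 and adjusted p = 0.108 with an estimated correlation; 1.2e-12 to 0.108 over the alternatives). The matricellular gene CCN1 fell from 72.3 to 51.2 CPM (log2 fold change -0.50, edgeR adjusted p = 4.4e-05), MYOF, which acts in membrane repair, fell from 29.5 to 18.4 CPM, and AMOTL2, a regulator of YAP, fell from 82.6 to 60.4 CPM. The word was present in 3 of the 12 fallen members, CCN1 among them. Of 26 tested immediate early and MAPK feedback genes 1 rose and 7 fell, or 2 and 8 adjusted over the list alone, with a median of -0.19 (camera adjusted p = 0.0054 and adjusted p = 0.55 with an estimated correlation; 2.4e-04 to 0.549 over the alternatives). SPRED2, an inhibitor of the MAPK pathway, fell from 40.5 to 24.8 CPM (log2 fold change -0.71), the transcription factor ETV5, the only fallen member with the word, fell by 0.97 on the log2 scale and JUN fell by 0.68, while NR4A2 rose from 0.693 to 2.0 CPM. The list's fry adjusted p was 0.0559, and it held 2 rises without shGXYLT2 replicate 2 or 3.

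Wnt targets were tested as lower, with a median log2 fold change of 0.025 and a mean of -0.081, which differ in sign; the median ran from -0.041 to 0.062 with 1 library left out. Of 19 tested members 2 rose and 6 fell, or 3 and 7 adjusted over the list alone (camera adjusted p = 0.0352 and adjusted p = 0.55 with an estimated correlation; 0.0134 to 0.549 over the alternatives). DKK1, BMP4 and APCDD1, an inhibitor of Wnt signalling that fell from 91.4 to 65.4 CPM, were among the falls. RNF43, a ubiquitin ligase that removes Wnt receptors, rose from 0.760 ± 0.446 to 3.01 ± 0.248 CPM (SD, n = 3 each; edgeR adjusted p = 2.3e-04), and NKD1, a negative regulator of the pathway, rose from 214 to 263 CPM (adjusted p of 2.8e-06 to 0.0502 over the alternatives). The word was present in 2 of the 6 fallen members. The list's adjusted p was 0.0637, 0.0503 and 0.0922 without shControl replicate 1, shGXYLT2 replicate 1 and shGXYLT2 replicate 2, 0.265 with limma-voom, 0.0505 with a filter at 1 CPM, 0.0529 among protein-coding genes, 0.0531 with GC content and length offsets and 0.15 among genes without the word.

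Of 36 tested genes of the unfolded protein response and ATF4 targets 0 rose and 13 fell, or 0 and 17 adjusted over the list alone, with a median log2 fold change of -0.15 (camera adjusted p = 5.2e-05 and adjusted p = 0.55 with an estimated correlation; 1.1e-07 to 0.549 over the alternatives). DDIT3, the stress-induced transcription factor CHOP, fell from 22.8 ± 0.863 to 11.6 ± 1.43 CPM (SD, n = 3 each; edgeR adjusted p = 1.6e-06). The cystine transporter SLC7A11 fell from 132 to 82.7 CPM and EDEM1, which acts in disposal of misfolded glycoproteins, fell from 76.3 to 55.0 CPM; these were the 2 fallen members with the word. The falls numbered 7, 6, 8 and 7 without shControl replicates 1, 2 and 3 and shGXYLT2 replicate 2, and 1 member rose without shGXYLT2 replicate 3. Of 35 tested genes of hypoxia and glycolysis 1 rose and 9 fell, or 2 and 13 adjusted over the list alone, with a median of -0.13 (camera adjusted p = 4.6e-04 and adjusted p = 0.55 with an estimated correlation; 5.1e-06 to 0.549 over the alternatives). The glucose transporter SLC2A3 fell from 54.5 to 35.2 CPM (log2 fold change -0.63, edgeR adjusted p = 1.1e-05), the glycolytic enzyme ENO2 fell from 32.4 to 21.9 CPM and EGLN3, a prolyl hydroxylase, rose from 27.1 to 40.1 CPM. By fry this list had an adjusted p of 0.0548. The word was present in 2 of the 9 fallen members, and 3 members rose without shGXYLT2 replicate 3.

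Of 29 tested interferon response genes 9 rose and 0 fell, or 11 and 0 adjusted over the list alone. Their median log2 fold change was 0.37 (camera adjusted p = 5.7e-05, and 0.108 with an estimated correlation). Over the alternatives the list's camera or fry adjusted p ran from 4.6e-06 to 0.108. IFIT2, which restrains translation of viral RNA, rose from 1.04 ± 0.283 to 2.59 ± 0.365 CPM (SD, n = 3 each; edgeR adjusted p = 0.0014), and PSMB9, an immunoproteasome subunit, rose from 3.37 to 6.11 CPM. IFIT1 rose from 3.27 to 5.59 CPM (edgeR adjusted p of 2.8e-04 to 0.0752 over the alternatives). The summed level of 18 leukocyte markers, none of which reached the test, was 1.38 ± 0.362 CPM in shControl and 1.71 ± 0.109 CPM in shGXYLT2 (SD, n = 3 each). Without shControl replicate 3 the rises numbered 5.

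Of 55 tested cytosolic ribosomal protein genes 10 rose and 0 fell, also adjusted over the list alone, with a median log2 fold change of 0.099 (camera adjusted p = 1.8e-05 and adjusted p = 0.66 with an estimated correlation; 1.2e-10 to 0.664 over the alternatives). RPS27A, which encodes ubiquitin fused to a ribosomal protein, rose from 906 ± 19.8 to 1086 ± 99.2 CPM (SD, n = 3 each; edgeR adjusted p = 0.0089). Its adjusted p was 0.055 and 0.051 without shControl replicate 3 and shGXYLT2 replicate 2 (9.3e-05 to 0.179 over the alternatives). GC content and length offsets lowered the list's median to 0.042 and ended its call (adjusted p = 0.0892), as did fry (adjusted p = 0.20). The median was 0.066 without shGXYLT2 replicate 3. Members that rose numbered 1, 1 and 0 without shControl replicates 1, 2 and 3, 16 without shGXYLT2 replicate 1 and 1 without shGXYLT2 replicate 2. Of 43 tested nuclear genes of oxidative phosphorylation 6 rose and 0 fell, or 10 and 0 adjusted over the list alone, with a median of 0.11 (camera adjusted p = 5.4e-05 and adjusted p = 0.57 with an estimated correlation; 1.5e-08 to 0.573 over the alternatives). NDUFB5, a subunit of complex I that carried the word, rose from 60.8 to 77.2 CPM (edgeR adjusted p = 0.0036). With the offsets the median was 0.063 and the adjusted p 0.0468, and fry gave 0.144. The rises numbered 1 without shControl replicate 1, 2 or 3 and 10 without shGXYLT2 replicate 1.

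Of 13 tested mitochondrially encoded genes 2 rose and 1 fell, or 3 and 1 adjusted over the list alone, with a median log2 fold change of 0.18 (camera adjusted p = 0.0352 and adjusted p = 0.66 with an estimated correlation; 9.7e-07 to 0.664 over the alternatives). MT-CYB, the cytochrome b of complex III, rose from 2403 to 2829 CPM (edgeR adjusted p = 0.0048, 0.064 without shControl replicate 1 and 1.1e-04 to 0.195 over the alternatives). The list's adjusted p was 0.0637, 0.286 and 0.0706 without shControl replicate 1, shGXYLT2 replicate 2 and shGXYLT2 replicate 3, 0.642 with GC content and length offsets, 0.0532 among protein-coding genes and 0.263 with fry. The median was 0.090 without shGXYLT2 replicate 2 and 0.068 with the offsets. The rises numbered 0, 1, 6 and 1 without shControl replicates 1 and 2 and shGXYLT2 replicates 1 and 2, and 0 members fell without shControl replicates 1 or 2 or shGXYLT2 replicate 1. Of 12 tested replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail, 4 rose and 0 fell, or 5 and 0 adjusted over the list alone, with a median of 0.33 (camera adjusted p = 0.0146 and adjusted p = 0.55 with an estimated correlation; 0.0031 to 0.549 over the alternatives). H2AC6 rose from 1.82 to 3.35 CPM (edgeR adjusted p = 0.010, 0.066 without shControl replicate 1 and 0.0017 to 0.0665 over the alternatives). The list's adjusted p was 0.0706 without shGXYLT2 replicate 3, 0.115 with the offsets and 0.0552 among genes without the word. The rises numbered 0, 1, 2 and 2 without shControl replicates 1 and 3 and shGXYLT2 replicates 2 and 3.

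**Figure D4:**
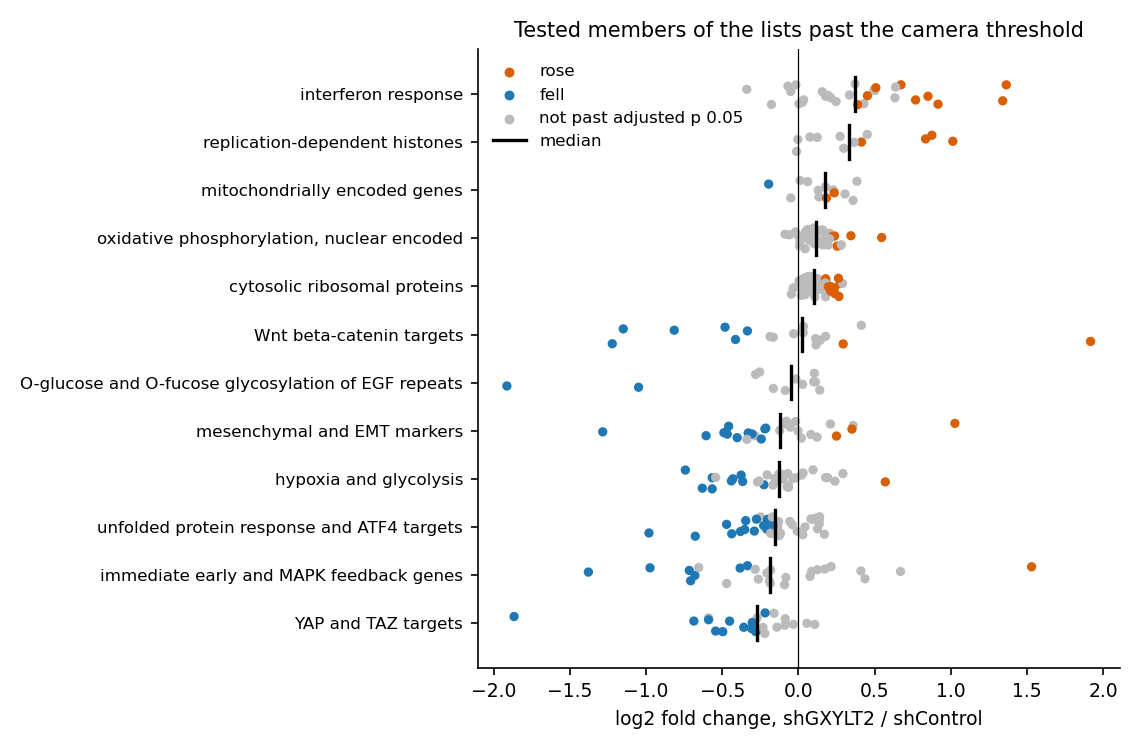
Log2 fold change, shGXYLT2 over shControl, of each tested member (points; rises orange, falls blue, others grey) of the 12 lists past the camera threshold, with the list median as a black line. Medians run from -0.27 for YAP and TAZ targets to 0.37 for the interferon response.

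Of 31 fixed lists 29 had enough tested members, and 12 passed camera with its preset correlation, 5 upward and 7 downward. With an estimated correlation 0 of them held (limma camera, lowest adjusted p = 0.108), with 3 at an unadjusted p below 0.05. The estimate was -7.7e-05 for the interferon response and -0.032 for EGF repeat glycosylation, both below the preset of 0.01. These values argue against a higher correlation as the reason that these lists lost their call. The rest of the 12 had estimates above the preset, from 0.025 for YAP and TAZ targets to 0.646 for mitochondrially encoded genes. Since lists with estimates below the preset lost their call too, the losses of the rest do not show that gene correlation caused them. By fry, which tests whether the genes of a list move on balance one way and does not compare them with other genes, 7 lists passed, 6 of them among the 12; 27 passed its mixed form, which tests for change in either direction.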

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

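Testing only genes without the 3' UTR word and counting lists at an unadjusted p were chosen after the results were seen. GXYLT2 stayed lower in every alternative, with log2 fold changes of -2.00 to -1.86 and adjusted p of at most 1.2e-07. The 1907 changed genes became 3017 with GC content and length offsets and 403 in a test against a 1.2-fold change, and 960 to 2347 with 1 library left out. The 195 genes changed at least 2-fold became 125 with the DESeq2 test and 126 among genes without the word. The 12 lists past camera became 0 with an estimated correlation (3 at an unadjusted p), 7 with fry, of which 6 were among the 12, and 7 among genes without the word, and 9 to 13 with 1 library left out. The fit without the word also left out genes without a searched 3' UTR, so 11340 genes were tested, against 15693 in the main fit. Its counts of genes and lists therefore do not show the effect of the word alone. The cause of the other moves was not tested. For the interferon response and EGF repeat lists, estimated correlations below the preset argue against a higher correlation as the reason for their loss.

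Over all lists and alternatives, 604 list tests stayed on their side of the threshold, 52 lost a call, 8 gained one and 0 called ones reversed; 30 tests, in 8 lists, had the other sign with no call in either fit. Among 124 named genes other than GXYLT2, 201 of the compared values lost a call, 1 gained a call and 2236 did neither, and 39 genes lost their call with at least 1 library left out. The camera adjusted p of the EGF repeat list (5.9e-04) was 0.10 with limma-voom, 0.155 with an estimated correlation and 0.156 without GXYLT2, its strongest member. It was 0.0631 among genes without the word, a fit that kept GXYLT2 but left out GXYLT1. The mesenchymal list (0.0324) was at 0.0712 with a filter at 1 CPM, 0.169 with the block by description number, 0.107 among genes without the word, 0.549 with an estimated correlation, 0.0559 with fry and 0.0055 to 0.103 with 1 library left out. The list of matrix proteases and invasion (0.153) was at 0.0279 to 0.482 with 1 library left out, and the stemness list (0.225) at 0.0415 with fry.

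The replicate numbers of the titles did not pair the libraries. Deviations of same-numbered libraries from their group means correlated at -0.017, -0.211 and -0.263 over 10046 genes, and no library correlated best with its own number. With these numbers as a replicate block 1471 genes passed, and 2465 with the block and GC content and length offsets. The descriptions number the libraries differently, and a block by those numbers gave 1410 genes. In that block shControl replicate 2 and shGXYLT2 replicate 2 shared a number with no other library. They therefore added nothing to the comparison, and the calls lost or gained with it rest on fewer libraries. With that block the adjusted p of the lists of immediate early genes (0.238), hypoxia (0.0679), Wnt targets (0.233) and mitochondrially encoded genes (0.233) also lost the threshold, and with the block by title number that of Wnt targets (0.0502), while nuclear RNAs gained a call with the former (9.3e-04); the cause was not tested.

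At depths of 17291138 to 24898425 counts, simulated changes of 1.5-fold were found in 77.6% of genes with a shControl mean of at least 1 CPM. Weaker genes were not tried. DESeq2 gave no adjusted p for 1522 genes, which were left out of its counts. Every alternative fixed before the data were examined was run.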

Other observations

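The shares of falls without the 3' UTR word or overlapping words, the GXYLT1 comparison and the leukocyte comparison were tests chosen only after the results were seen, as were the low-level genes named next. Several weakly expressed genes also changed severalfold. CALB2, the calcium-binding protein calretinin, rose from 0.257 ± 0.113 to 2.44 ± 0.296 CPM (SD, n = 3 each; 9.70-fold, edgeR quasi-likelihood adjusted p = 2.5e-06). The cadherin CDH10 rose from 2.85 to 10.8 CPM and SEMA6D, a semaphorin, from 0.830 to 3.59 CPM. CDH13, a cadherin anchored by a lipid, fell from 5.20 ± 0.244 to 1.12 ± 0.239 CPM (SD, n = 3 each; 4.63-fold lower, edgeR adjusted p = 3.1e-07), and AKR1C3, an aldo-keto reductase of steroid metabolism, fell from 1.31 to 0.293 CPM.

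The remaining lists did not pass camera in the fit to all libraries. Of 25 tested cholesterol synthesis genes 2 rose and 5 fell, or 2 and 6 adjusted over the list alone (camera adjusted p = 0.0881; 0.0119 to 0.997 over the alternatives). CYP51A1, a sterol demethylase, fell from 60.6 to 35.4 CPM and STARD4, a sterol carrier, fell from 76.0 to 37.1 CPM, both among the 3 fallen members with the word. The list's adjusted p was 0.0119 without shGXYLT2 replicate 3 and 0.0263 with GC content and length offsets. Its falls numbered 2 without shControl replicate 1, 2 or 3 and 3 without shGXYLT2 replicate 2, and its rises 0, 0, 1 and 1 without shControl replicates 1, 2 and 3 and shGXYLT2 replicate 1. Of 33 tested glycosyltransferases of other pathways 3 rose and 5 fell, also adjusted over the list alone (adjusted p = 0.225). XYLT1, which starts glycosaminoglycan chains, rose from 35.8 to 47.1 CPM, and OGT, which adds O-linked N-acetylglucosamine, fell from 333 to 270.4 CPM. The list held 1 rise without shControl replicate 1 or shGXYLT2 replicate 1 and 3 falls without shControl replicate 1. Of 28 tested CDK inhibitors and p53 targets 2 rose and 7 fell, or 5 and 7 adjusted over the list alone (adjusted p = 0.494); CDKN2B, an inhibitor of CDK4, fell from 21.5 to 15.6 CPM. The rises numbered 0 without shControl replicate 1, 2 or 3 and 1 without shGXYLT2 replicate 1, and the falls 4 without shControl replicate 2 or 3 or shGXYLT2 replicate 2.

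Of 33 tested apoptosis regulators 1 rose and 4 fell, or 2 and 4 adjusted over the list alone (camera adjusted p = 0.991, direction down, with a positive median of 0.005 and mean of 0.043; the direction was up without shControl replicate 1 or shGXYLT2 replicate 2). XIAP, a caspase inhibitor that carried the word, fell from 62.7 to 39.9 CPM. The rises numbered 0 without shControl replicate 1, 2 or 3 or shGXYLT2 replicate 1 and 2 without shGXYLT2 replicate 3. Of 22 tested TGF-beta response genes 2 rose and 5 fell, or 3 and 5 adjusted over the list alone (adjusted p = 0.770, direction down, median 0.006, mean -0.080; with 1 library left out the median ran from -0.056 to 0.012, and the direction was up without shGXYLT2 replicate 2). LTBP1, which binds latent TGF-beta, rose from 318 to 441 CPM and THBS1, the matricellular protein thrombospondin 1, fell from 60.9 to 37.7 CPM. The falls numbered 3 without shControl replicate 1, 2 or 3 or shGXYLT2 replicate 2, and the rises 5 without shGXYLT2 replicate 2. Of 13 tested NF-kB and cytokine genes 3 rose and 1 fell, or 3 and 2 adjusted over the list alone (adjusted p = 0.494), and the inhibitor NFKBIA rose from 23.0 to 35.8 CPM. The falls numbered 2 without shControl replicate 1 or shGXYLT2 replicate 1 or 3. Of 9 tested nuclear RNAs 0 rose and 2 fell, or 1 and 3 adjusted over the list alone (adjusted p = 0.213; 9.3e-04 to 0.664 over the alternatives), and it was 0.0258 without shControl replicate 2. The falls numbered 0, 0 and 1 without shControl replicates 1 and 3 and shGXYLT2 replicate 1.

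Of 8 tested gastric lineage genes 1 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.991, direction down, median -0.15, mean 0.044; the direction was up without shControl replicate 1 or 2 or shGXYLT2 replicate 3). The gastric mucin MUC6 rose from 2.05 to 4.22 CPM. KLF5 fell, a call lost with any of the 6 libraries left out, and 2 members rose without shControl replicate 2. Of 13 tested fibroblast markers, all but 1 of the list, 3 rose and 4 fell, or 4 and 5 adjusted over the list alone (adjusted p = 0.882, direction down, median 0.019, mean -0.16; with 1 library left out the median ran from -0.033 to 0.069, and the direction was up without shGXYLT2 replicate 3). DCN, a proteoglycan that carried the word, rose from 186 to 250.4 CPM, and MFAP5, a microfibril protein that also carried it, fell from 3.10 to 1.34 CPM. Of 4 tested endothelial markers 0 rose and 1 fell, also adjusted over the list alone: FLT1, a VEGF receptor with the word, fell from 0.893 to 0.169 CPM (edgeR adjusted p = 0.0011).

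Genes other than the target fell, GXYLT1 among them, and many of them shared a 3' UTR word. Off-target repression through a seed match of the shRNA is a candidate explanation for part of the falls: the word GACTCAT, chosen in a random part of the genes, had a t of -8.82 and rank 1 of 16153 words in the other part, and it lies in GXYLT2 transcripts, as it would in 18% of random sequences as long as the longest. The word alone gives no account of the falls that lack it: it was absent from 74.6% of the fallen genes with a searched 3' UTR. Falls with it above the rate of genes without it numbered 180.1, or 18.6% of the searched falls. That share was not adjusted for the length of the 3' UTR and includes the genes on which the word was chosen. Overlapping words that share 6 of its bases also went with falls, TGACTCA (t = -5.71), ACTCATA (t = -5.54) and AGACTCA (t = -4.77), with t of -2.41, -0.90 and -1.45 among genes without GACTCAT. Of the searched falls 50.9% held none of the 4 words, and falls with any of them above the rate of genes with none numbered 290.8, or 30%, with no adjustment for the length of the 3' UTR. Reads counted for GXYLT2 were too few to make up the fall of GXYLT1, which lost 37.9 CPM while the whole GXYLT2 level in shControl was 21.3 CPM. GXYLT2 reads that the counting gave to GXYLT1 are not part of that level, so the comparison cannot exclude them. An effect of lower GXYLT2 itself was not tested and stays open, with a single shRNA of unstated sequence; the real split of the libraries gave 1907 genes and the highest other 0 by edgeR (207 to 818 at an unadjusted p below 0.05), 1 of 10 splits, too few for a share under 0.05.

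The small upward shifts of the ribosomal protein and oxidative phosphorylation lists may come from GC content and length differences between libraries. The offsets kept 42.4% of the median of the ribosomal protein list and 56.0% of that of oxidative phosphorylation, on either side of the bound set for this explanation, so it cannot be told apart from a change in the cells. Variation between libraries of a group also stays open: the lowest shGXYLT2 library mean lay 0.001 log2 CPM above the highest shControl one for ribosomal proteins, against a range of 0.17 within a group, and 0.032 against 0.163 for oxidative phosphorylation. An effect of the knockdown was not tested apart from these.

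The rise of interferon response genes did not rest on a single library: with any 1 left out between 5 and 10 of the tested members rose, against 9 in all libraries, and the lowest list median was 0.267. Leukocyte RNA is an unlikely source: the 18 markers were higher by 0.335 CPM in sum, against 33.2 CPM for the interferon list, and no marker averaged above 0.393 CPM in either group (PTPRC was highest in shControl at 0.389, and CD74, at 0.068 there, in shGXYLT2). The interferon sum was 477 ± 15.1 CPM in shControl and 510 ± 19.9 CPM in shGXYLT2 (SD, n = 3 each). IFIT2, PSMB9 and IFIT1 averaged at most 6.11 CPM, so that sum does not measure their rise alone. A response to the shRNA itself and an effect of lower GXYLT2 were not tested and stay open.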
